A study of Drosophila melanogaster and Drosophila erecta with 20 samples.

How the data were processed

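The samples were ovaries of Drosophila melanogaster grown at 24 °C, with RNA extracted by Trizol per the labels' protocols, together with 1 library from D. erecta and 1 from a Piwi immunoprecipitate. Each of 9 loci had 1 mutant and 1 heterozygote library, and groups were taken from the sample titles. For each library the authors deposited a table of distinct small RNA sequences with their counts, the number of reads of each sequence. Per the file headers another column, of a unit other than counts, holds the length of each sequence in nt. Per the file names these are the sequences that did not map. The genome build, the aligner, the mismatch limit, the trimming and the length filter were not given in the sources used here. No counts of mapped reads and no library totals were used, so the sum of a file is not the depth of the library.

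The content was tested on the files. Of 26 listed mature RNAs (25 microRNAs and 2S rRNA), 0 were present as exact sequences in any of the 18 total RNA files of D. melanogaster, while near matches were abundant, so the files hold sequence variants and sequence the mapping did not place. The mature sequences were written from general knowledge and not taken from a reference, 20 of the microRNAs as planned and 5 (miR-2a, miR-13b, miR-9b, miR-14 and miR-282) added after abundant sequences had been seen. In the Piwi immunoprecipitate 9341 rows state a length that differs from that of the sequence, and the length of the sequence itself was used. The krimp and vasa libraries and the squ mutant have between 1322032 and 1797186 distinct sequences, and the other 13 total RNA libraries of D. melanogaster between 261629 and 462259. This split was treated as a kind of library, and the 6 measures compared over pairs were recomputed within it. Reads of 18 to 30 nt numbered at least 314120 in each of the 18 libraries, so that 95% intervals reached at most 0.173 points from the share of 23 to 29 nt reads and 0.127 points from that of 2S rRNA.

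Reads of 18 to 30 nt were counted as small RNA and those of 23 to 29 nt as piRNA length. A read was assigned to a microRNA when 16 bases from its 5′ end matched with up to 2 mismatches, allowing an offset of 2 nt, and to 2S rRNA when 18 bases matched with up to 2 mismatches. Reads matching several microRNAs equally well were not assigned. The same search with reversed reads assigned at most 0.0169% of reads to microRNAs. Sequences of 21 nt were assembled into contigs with 17-base words seen at least 4 times, and contigs of at least 100 bases were kept. The ping-pong signature compares the first 10 bases of each 23 to 29 nt read with the complement of 10 bases of every other read, for overlaps of 10 to 23 nt, over the frequency expected from the base composition at each position. The value at 10 nt was divided by the median of the longer overlaps, after leaving out reads assigned to microRNAs, 2S rRNA or contigs. It replaces the planned measure on aligned reads, and it and the reads left out were chosen after the files had been seen. In simulated reads with 0, 2, 5 or 10% of reads given a partner it was 1.01, 1.38, 1.88 and 2.62.

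Tags were the first 20 bases of 23 to 29 nt reads, without the reads named above, and replace transposon families. Tags with at least 20 reads in all numbered 21547, and filterByExpr kept 9018. Counts were tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by the quasi-likelihood test, with the locus as block, 1 mutant effect per locus class, squ as an effect of its own, and all 18 to 30 nt reads as library size. The test was tried on simulated counts for the 9018 tags at the germline loci, with 200 tags changed. A first simulation with 2-, 4- and 8-fold changes recovered 0% of them and made 0 calls. After that result larger folds were simulated, and 8.57% of 8-fold, 85.7% of 32-fold and 97.5% of 128-fold rises were recovered, as were 7.32%, 12.9% and 20.0% of falls of those sizes, with 0 of 78 calls wrong. Most simulated changes of 8-fold or less, and most simulated falls of up to 128-fold, were therefore missed. MicroRNA counts of 18 to 25 nt reads were tested with TMM scaling and 1 mutant effect, and simulated 2-fold and 4-fold changes of 4 of the 25 microRNAs were recovered in 72.5% and 100% of cases, with 0.18 and 0.14 wrong calls per simulation. DESeq2 1.42.0 was the alternative. P-values were adjusted by the Benjamini-Hochberg method. The errors of the microRNA folds are standard errors of the log2 ratios over pairs, with 1 added to reads per 1000000.

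Single values were compared across pairs by an exact sign-flip permutation test and between classes by exact permutation of the loci, two-sided except for the similarity of tag responses, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The heterozygote spread was examined by Dixon's rule. Intervals are exact binomial intervals at 95%.

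The groups, the tests, the RNA lists and the alternatives of the first plan were chosen before the data were examined. Once the files proved to hold unmapped sequences only, the tags, the flam and aub tag sets, the similarity of tag responses, the contigs, the comparison of 5′ ends, the family of abundant sequences, the reads over 30 nt, the class tests of measures other than ping-pong and 20 further alternatives were added. Named items were the measured members of the planned lists and the added microRNAs. The plan named up to 8 transposon families in each direction, and in their place the 2 tags with the largest fold in each direction are given by their folds only. Alternatives covered the length class, distinct sequences in place of reads, the scaling, the filter, the tool, the class of squ and each locus left out. Families of transposons, soma and germline family lists, piRNA clusters, genic piRNA loci, hairpin siRNA loci and tRNA, snoRNA and snRNA fragments need a genome or an annotation and were not analysed here.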

Results

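Small RNAs from fly ovaries were sequenced in 20 libraries, 18 of them from Drosophila melanogaster total RNA. Mutants of 9 loci of the piRNA pathway were each set beside heterozygotes for the same locus, with 1 library per genotype. PiRNAs are small RNAs of about 23 to 29 nt that guide Piwi proteins to transposon transcripts. The germline loci were aub, krimp, spnE and vasa. The loci known to act in the somatic follicle cells were armi, flam, piwi and zuc, called the other loci or the soma and germline loci below. Flam, the main piRNA cluster of the follicle cells, is in that class for its role there, and the name implies no role of flam in the germline. These classes come from work on the loci that includes this study and are therefore not independent of these samples, and squ was placed in neither class. Of the remaining libraries, 1 held small RNAs bound to Piwi in armi mutants and 1 came from Drosophila erecta. The deposited files hold the distinct sequences that did not map, with a read count for each, so every value below describes the unmapped part of a library and not its piRNA content. Reads of 18 to 30 nt numbered between 314120 and 966221 in the 18 libraries, 80844 in the Piwi immunoprecipitate and 2099934 in D. erecta. With 1 library per genotype no pair has a replicate check, and the loci serve as the units of each test. Intervals on single libraries cover counting error only. Whether a mutant library carries its mutation could not be checked in unmapped small RNAs.

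Unmapped small RNAs of piRNA length began with uridine less often in 8 of 9 mutants, the first base that piRNAs bound by Piwi and Aub mostly carry. In the flam mutant the share of 23 to 29 nt reads beginning with U was 43.4%, against 72.3% in its heterozygote, in the piwi mutant 34.9% against 62.3%, and in the aub mutant 39.2% against 67.5%. In vasa it was 60.1% against 73.1%, in zuc 54.4% against 69.3%, in squ 67.6% against 77.3%, in spnE 57.5% against 65.6% and in krimp 60.2% against 64.3%. The armi mutant was the exception, at 66.7% against 65.4%, but it too was lower by distinct sequences (-0.801 points), at 24 to 28 nt (-2.24) and without microRNA, 2S rRNA and contig reads (-3.56), and higher without the A-starting family (2.81). In aub much of the fall came from 1 family of abundant sequences beginning with A, without which the mutant had 53.3% against 67.5%, and by distinct sequences it had 56.4% against 63.2%. Over the 9 pairs the difference averaged -14.8 points (SD 11.1, n = 9 pairs), and 8 pairs were lower.

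The exact sign-flip permutation test gave p = 0.0078 (two-sided, smallest possible 0.0039, adjusted to 0.016 over the 6 measures compared across pairs). The 6 pairs whose files were both of the smaller kind had a mean difference of -17.7 points with an exact p of 0.062, and the 2 pairs with larger files had -8.54 points. The 9 heterozygotes ranged from 62.3% to 77.3%, with an SD of 4.87 points, and no 95% exact binomial interval reached farther than 0.216 points from its value. No difference between the locus classes was resolved, at 4.14 points by an exact permutation p of 0.63.

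The length profile moved less. Reads of 23 to 29 nt made up 53.3% of 18 to 30 nt reads in the zuc mutant and 70.9% in its heterozygote, 55.3% against 68.1% in spnE, and 56.7% against 68.1% in krimp. Among the 9 pairs 8 were lower in the mutant, and the aub pair went the other way, with 75.3% in the mutant and 49.8% in the heterozygote, a library in which 27.5% of reads were exactly 21 nt long. The mean log2 ratio was -0.11 (SD 0.29, n = 9 pairs; exact sign-flip p = 0.30). With each distinct sequence counted once it was -0.22 at an exact sign-flip p of 0.016, with 7 pairs lower.

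**Figure D1:**
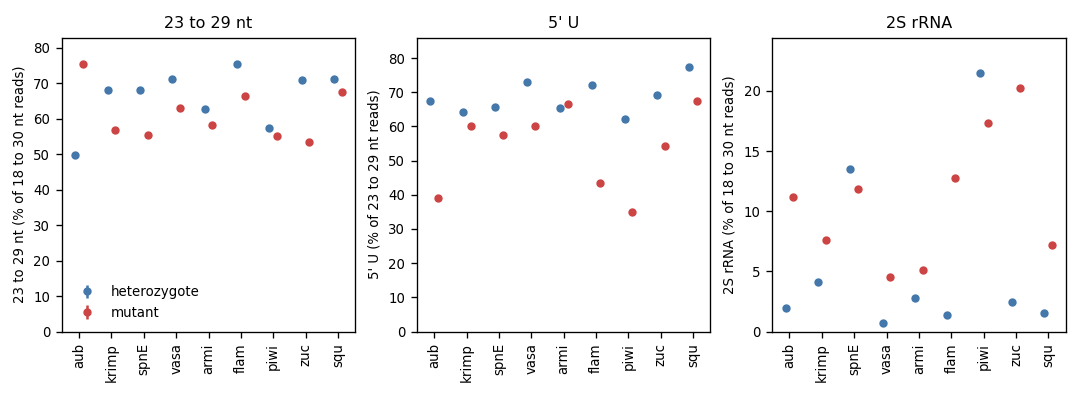
Share of 23 to 29 nt reads, share of these beginning with U, and share of 2S rRNA reads (y axes, percent) in the heterozygote (blue) and mutant (red) library of each locus (x axis), with 95% exact binomial intervals that are narrower than the points. The 5′ U share of the flam, piwi and aub mutants lies between 34.9% and 43.4%, and that of the 9 heterozygotes between 62.3% and 77.3%.

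Fragments of 2S rRNA, a ribosomal RNA of 30 nt that is common in fly small RNA libraries, rose in mutants. They made up 20.2% of 18 to 30 nt reads in the zuc mutant and 2.42% in its heterozygote, 12.8% against 1.41% in flam and 11.2% against 1.97% in aub. The piwi and spnE pairs had high shares in both libraries, 17.4% in the piwi mutant and 21.5% in its heterozygote, and 11.9% and 13.5% in spnE. The mean log2 ratio was 1.65 (SD 1.36, n = 9 pairs), with 7 pairs higher and an exact sign-flip p of 0.016 (adjusted to 0.023). Sequences longer than 30 nt were also more frequent in all 9 mutant files, by 18.6 points on average (SD 15.2; exact sign-flip p = 0.0039). In squ, whose mutant file is of the larger kind and whose heterozygote file is not, the 51.1 points go with a difference in the kind of library, while the 6 pairs of smaller files averaged 16.9 points (exact sign-flip p = 0.031, the smallest possible) and krimp and vasa 14.4 and 0.479.

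Within the 6 pairs with smaller files the 2S ratio averaged 1.52, with an exact p of 0.13, and in the 2 pairs with larger files 1.75. Transfer, small nucleolar and small nuclear RNA fragments were not analysed here.

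Complementary 5′ ends, the mark of the ping-pong cycle in which Aub and Ago3 piRNAs of opposite strands overlap by 10 nt, were nearly lost in the spnE mutant and reduced in the aub and vasa mutants. The signature is the frequency of reads whose first 10 bases are complementary to those of another read, over that at longer overlaps, so that 1 means no excess at 10 nt. It was 1.07 in the aub mutant and 5.13 in its heterozygote, 1.06 against 4.94 in spnE and 2.66 against 6.69 in vasa. The aub value depended on the definition, with 1.47 against 3.61 by distinct sequences and 0.48 against 5.09 with the mean of the longer overlaps. By reads, observed over expected in the aub mutant was 0.39 at 10 nt and 4.52 at 20 nt. The family of abundant sequences beginning with A was not left out of this measure. In the other class the signature was higher in each mutant than in its heterozygote, at 15.0 against 6.48 in zuc, 7.55 against 3.90 in armi, 5.63 against 4.95 in flam and 6.48 against 5.91 in piwi. The rises in piwi and flam were small and changed sign with other definitions. The piwi mutant had 4.61 against 5.10 with microRNA, 2S rRNA and contig reads kept, 5.56 against 5.76 with the mean of the longer overlaps and 5.77 against 6.07 at 24 to 28 nt, and the flam mutant 4.55 against 4.65 with those reads kept. The squ mutant had 5.75 and its heterozygote 5.49, but 3.61 against 3.99 by distinct sequences and 4.62 against 4.98 without the most abundant complementary pair.

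The separation of the classes depended on the krimp pair. By reads the krimp mutant had 7.80 against 6.20, but 79.9% of its read products came from a single complementary pair of 10-base ends. With each distinct sequence counted once the krimp mutant had 1.69 and its heterozygote 4.35. By reads the mean log2 ratio was -1.37 (SD 1.22) over the 4 germline loci and 0.62 (SD 0.54) over the 4 other loci, a difference of -1.99 with an exact permutation p of 0.086 (two-sided, 70 splits). This difference by reads misses 0.05 and stays the main value, since reads and this permutation were fixed in advance, although the signature was redefined without alignments after the files had been examined. Of the settings chosen in advance, distinct sequences gave -2.15 at an exact permutation p of 0.029, the smallest these splits allow, and squ among the germline loci 0.063. The 7 chosen later gave exact permutation p between 0.016 and 0.086. Over all 9 pairs the reads gave a mean of -0.33 (exact sign-flip p = 0.51), with 6 pairs higher and 3 lower. Krimp and vasa both came from libraries with larger files. Without them the difference was -2.87 by reads, with an exact permutation p of 0.067, the smallest that 2 loci against 4 allow.

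**Figure D2:**
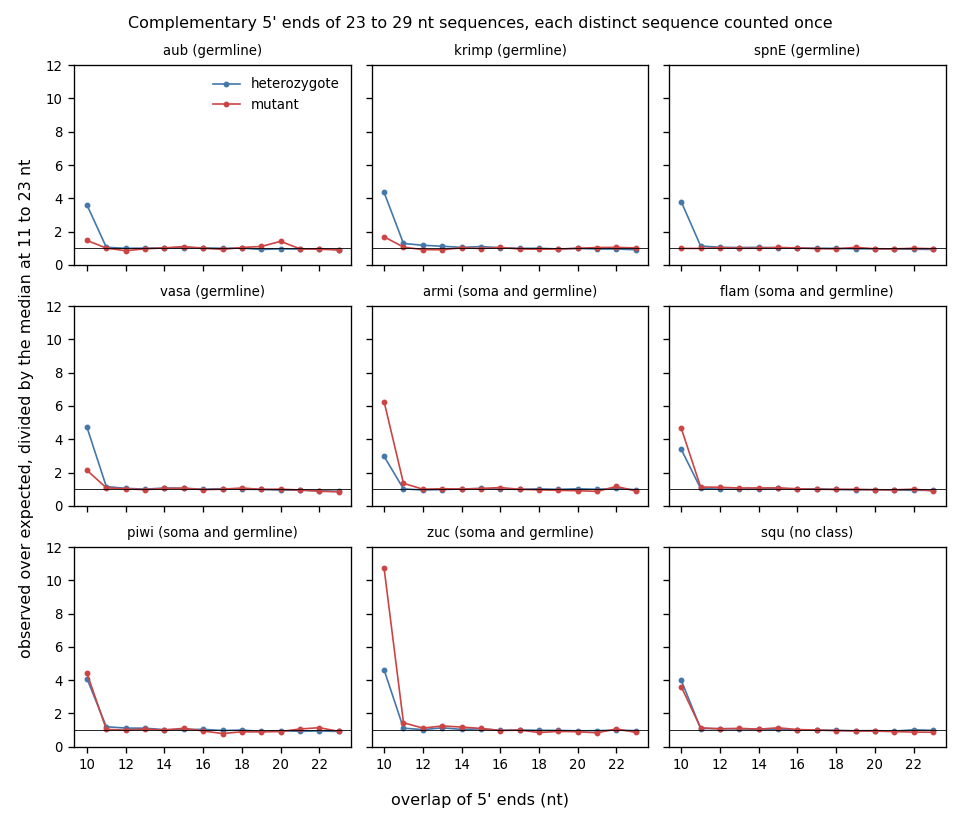
Frequency of complementary 5′ ends (y axis, observed over expected, divided by the median at overlaps of 11 to 23 nt) against the overlap of the 5′ ends (x axis, nt) for each locus, heterozygote in blue and mutant in red, each distinct sequence counted once. The peak at 10 nt in the aub, krimp, spnE and vasa mutants is 1.47, 1.69, 0.99 and 2.13, and in the zuc mutant 10.7.

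By reads, most individual piRNA-length sequences had a log2 fold below 0 in mutants of both classes. More of them were called lower at the germline loci, and at the other loci the shift was absent by distinct sequences. No transposon annotation was used, and the first 20 bases of 23 to 29 nt reads, called tags below, took the place of transposon families. Of 9018 tags, 2030 were lower and 375 higher in the mutants of aub, krimp, spnE and vasa by edgeR's quasi-likelihood test at an adjusted p of 0.05, and the median log2 fold over all tags was -1.55. In mutants of armi, flam, piwi and zuc 15 tags were lower and 67 higher, around a median of -0.68. The share of all tags with a log2 fold below 0 was 64.5% at the germline loci and 62.1% at the other loci. With each distinct sequence counted once, a setting chosen in advance, the median over 3578 tags was -1.13 at the germline loci. At the other loci that median was -4.97e-17, so no shift was seen, with 16 tags lower and 175 higher. By reads, both classes called 34 tags higher, where independent lists would share 2.79, and 11 lower, where they would share 3.38. The family of abundant sequences beginning with A, higher in all 9 mutants, was not left out of the tags. How many called tags belong to it was not counted, so several of the rises may be variants of 1 sequence. The tags with the largest log2 folds stood at -9.06 and -8.82 among those that fell at the germline loci, and at 8.34 and 8.25 among those that rose.

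The test of the difference between the classes itself called 0 tags with edgeR, 1199 at an unadjusted p under 0.05, and with DESeq2 2 higher and 256 lower at the germline loci, with 886 at an unadjusted p under 0.05. With each distinct sequence counted once, a setting chosen in advance that kept 3578 tags, edgeR called 2 higher and 240 lower at the germline loci, with 807 at an unadjusted p under 0.05. Whether the classes differ in single tags therefore depends on the tool and on how reads are counted. The calls rest on few loci. Without krimp and vasa the germline loci gave 0 tags in edgeR, with 1488 at an unadjusted p under 0.05, at a median log2 fold of -1.44, and without vasa alone 671 lower and 112 higher. Without aub they gave 145 higher, and without krimp or spnE 1126 or 1113 lower, all in edgeR. In the other class edgeR called 0 tags without flam, without piwi or without zuc (1204, 1004 and 990 at an unadjusted p under 0.05). It called 21 higher and 1 lower there without vasa, and 7 lower without spnE. Without armi it called 348 higher and 108 lower, and 52 tags also differed between the classes. Leaving out squ, which had an effect of its own, changed the filter, which kept 4256 tags in place of 9018. Over this smaller set the other class had 162 higher and 68 lower, a count not comparable with the others. DESeq2 called 267 higher and 289 lower in that class. With microRNA reads as the library size the germline loci had 2499 lower and 174 higher and the other class 0 lower and 3 higher, and the median log2 fold moved to -2.15 and to -0.15. The share of microRNA reads itself differed within most pairs, in both directions, so this scaling is not a level reference.

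Tags that fell in the flam mutant and tags that fell in the aub mutant differed in median by 1.94 to 4.53 in krimp, spnE and vasa, by 1.30 in armi and 1.53 in squ, and by -0.43 and -0.14 in piwi and zuc, so armi had the sign of the germline loci. The flam locus is the main piRNA cluster of the follicle cells, while Aub is a germline protein. A fall of at least 8-fold from at least 20 heterozygote reads picked 162 tags in flam and 236 in aub, with 12 in both, which were left out of both sets. Both sets were defined after the files had been examined. With 1 library per genotype, a loss of piRNAs cannot be told apart from a sequence difference between mutant and heterozygote stocks. The same holds for the tag calls above. The flam set stood below the other tags in piwi and zuc, by -0.88 and -0.87 in median log2 ratio, and less so in armi, by -0.34. It stood above them in krimp, vasa and spnE, by 1.97, 1.63 and 0.42. The other tags themselves fell there, with medians of -2.29, -2.09 and -2.38. Without that comparison the median of the flam set lay below 0 in every pair. In spnE it was -1.96, much as in piwi and zuc, at -2.01 and -1.90, and in armi -1.14. The difference of 0.19 between the flam set and the other tags in aub is raised by the choice, since tags that fell in both mutants were left out. The aub set stood below the other tags in vasa, spnE and krimp, by -2.91, -1.52 and -1.22, in armi and squ, by -1.63 and -1.71, and in zuc and piwi, by -0.74 and -0.45.

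The flam set differed between 4 germline loci and 3 other loci by 1.75 (means 1.05, SD 0.88, and -0.70, SD 0.31), with an exact permutation p of 0.057 against a smallest possible 0.029. The aub pair helped to shape this set, and without it the difference was 2.03 (exact permutation p = 0.10, the smallest possible), while with the tags of both sets kept it was 1.65 (exact permutation p = 0.057). With tags of at least 50 heterozygote reads, 1 of 3 other definitions of the sets tried, the difference was 2.12 at an exact permutation p of 0.029. The aub set differed between the classes by -1.19 (exact permutation p = 0.11), and without the flam pair by -0.95 (exact permutation p = 0.30). The median of the flam set minus that of the aub set was 3.22 (SD 1.30) at 3 germline loci and 0.24 (SD 0.93) at 3 others, where the exact permutation p of 0.10 is the smallest possible.

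**Figure D3:**
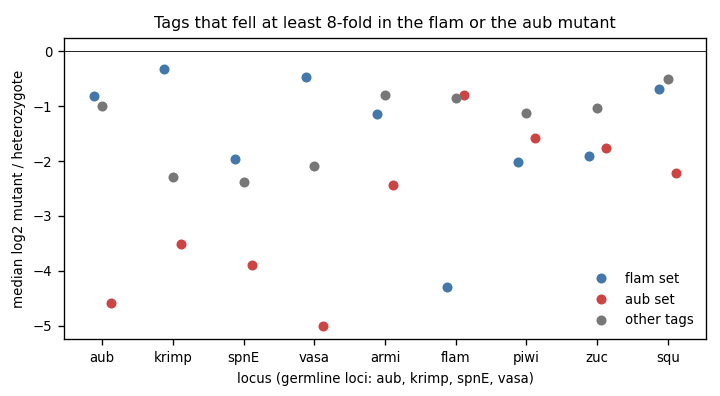
Median log2 ratio of mutant to heterozygote (y axis) in each locus pair (x axis) for the 150 tags of the flam set (blue), the 224 tags of the aub set (red) and the other tags (grey), in reads per 1000000 reads of 18 to 30 nt with 1 read added. The flam set was chosen in the flam pair, where its median is -4.29, and the aub set in the aub pair, where its median is -4.59, and tags that met the rule in both pairs were left out. In the vasa pair the aub set lies at -5.00 and the flam set at -0.47.

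Single microRNAs rose or fell in mutants, and no list was tested as a set. MicroRNAs are made without the piRNA pathway and served as a background. Of 25 microRNAs tested, 4 rose and 3 fell in mutants over the 9 pairs (edgeR's quasi-likelihood test with TMM scaling, adjusted p of 0.05). The median log2 fold was 0.10 with TMM and -0.04 with all 18 to 30 nt reads as library size, and let-7, miR-100, miR-125 and the 7 called kept their sign in both. Both members of the muscle and fat body list rose, miR-1 with a log2 fold of 1.75 (SE 0.35) and miR-277 with 1.16 (SE 0.33), each in 9 of 9 pairs. MiR-318 and miR-994, 2 members of the soma list, fell by 2.13 (SE 0.49; lower in 9 of 9 pairs) and by 0.94 (SE 0.37; lower in 8 of 9) on the log2 scale. The fall of miR-318 reached -4.65 in the piwi pair and -4.32 in the flam pair.

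The remaining members of the soma list went the other way. MiR-100 rose by 0.72 (SE 0.22; higher in 8 of 9 pairs), while let-7 had a log2 fold of 0.55 and miR-125 one of 0.57, with edgeR's adjusted p at 0.069 and 0.11. Of the 8 members of the germline list only miR-312 passed, with a log2 fold of -0.75 (SE 0.28; lower in 7 of 9). MiR-306, on the same list, fell by 0.78 (SE 0.35; lower in 8 of 9) at an adjusted p of 0.069 in edgeR, which was 0.0038 with no mismatches and 0.041 scaled by all 18 to 30 nt reads, and DESeq2 gave 0.0032. Without flam, spnE, vasa or zuc neither of them passed in edgeR. The general list had 1 call among 5 members, miR-8, which rose by 1.05 (SE 0.22) in 9 of 9 pairs, while bantam stood at 0.16. The adjusted p was 0.0012 for miR-1, 0.0015 for miR-318, 0.0052 for miR-8 and 0.0079 for miR-277 in edgeR, and 0.042 for miR-994 and miR-100 and 0.048 for miR-312. Scaled by all 18 to 30 nt reads, edgeR's adjusted p was 0.11 for miR-8, 0.14 for miR-994 and 0.10 for miR-100, and with no mismatches allowed it was 0.058 for miR-994 and 0.24 for miR-100. Leaving out flam, spnE or vasa left 1 microRNA lower, and without krimp, vasa and squ 2 were higher and 4 lower. No microRNA differed between the locus classes after adjustment (lowest exact permutation p 0.029, for miR-13b, adjusted to 0.56).

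**Figure D4:**
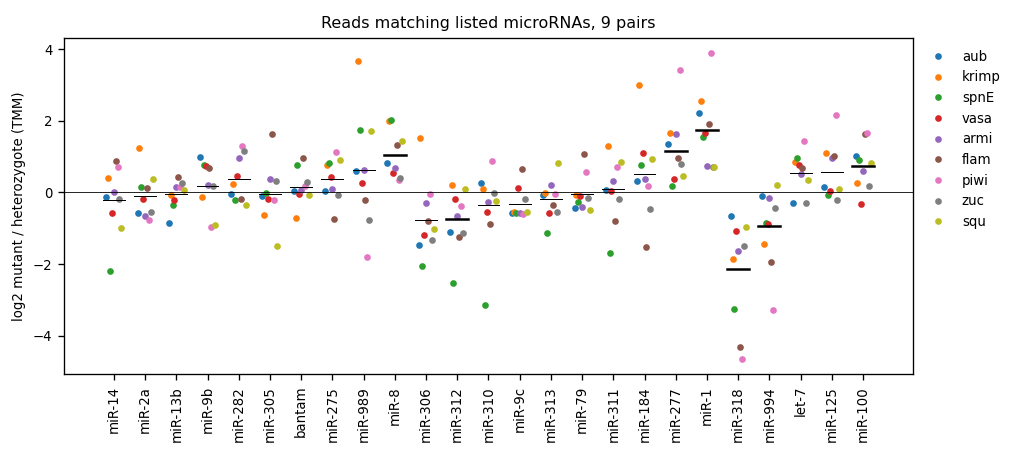
Log2 ratio of mutant to heterozygote reads (y axis, TMM scaling) for 25 microRNAs (x axis), 1 point per locus pair, with edgeR's log2 fold as a bar that is thick where the adjusted p is under 0.05. MiR-1 and miR-277 lie above 0 in all 9 pairs and miR-318 below 0 in all 9.

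Small RNAs bound to Piwi in armi mutants held few microRNAs and few of the tags that fell in the aub mutant. Listed microRNAs made up 1.62% of 18 to 30 nt reads in the immunoprecipitate and 24.8% in total RNA of armi mutants, and 23 to 29 nt reads 93.9% (95% exact interval 93.8% to 94.1%) and 58.3%. The share with 5′ U was 67.0% in the immunoprecipitate and 66.7% in total RNA of the mutant. The aub set made up 0.0435% of 23 to 29 nt reads (exact interval 0.0299% to 0.0610%) in the immunoprecipitate, 0.435% in total RNA of armi mutants and 1.32% in heterozygotes. The flam set made up 1.66% (exact interval 1.57% to 1.76%), 2.91% and 3.01%. The ping-pong signature was 1.25 in the immunoprecipitate and 7.55 in total RNA. These are single libraries without a test, and an immunoprecipitation changes the make-up of a library in itself.

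The D. erecta library was set beside the 9 heterozygotes as a species with its own set of transposons. Its share of 23 to 29 nt reads was 89.3%, above the heterozygotes' 49.8% to 75.2%, and its ping-pong signature of 3.34 lay below their 3.90 to 6.69. Its 5′ U share of 70.6% and its microRNA share of 14.6% lay within their ranges of 62.3% to 77.3% and 12.5% to 19.6%. Transposon families of D. erecta were not analysed here.

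Among the heterozygotes, each of a different locus, the ping-pong signature averaged 5.52 (SD 0.89, n = 9), the 23 to 29 nt share 66.0% (SD 8.04) and the 2S rRNA share 5.55% (SD 7.11, range 0.731% to 21.5%). Reads per transposon family and from the flam, 42AB, traffic jam and brat loci were not analysed here.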

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

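Among the tests here, those of the relation of rRNA fragments to the ping-pong signature over 18 libraries, of miR-1 to rRNA fragments and of 19 nt overlaps were chosen before their result was seen, and those of the most abundant complementary pair, the kind of library, dilution by listed reads, mismatches, other soma-list members, carry-over, open reading frames and other splits of the samples only after it.

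The ping-pong signature differed between the locus classes when each distinct sequence was counted once, by -2.15 on the log2 scale. An exact permutation of the class labels picked it up (p = 0.029) in a setting chosen in advance, which was looked at here only once the difference by reads, -1.99, had missed 0.05 at an exact permutation p of 0.086. By reads, the difference without the most abundant complementary pair of each library was -2.63 (exact permutation p = 0.029), so that pair did not produce it. This cannot decide the source of the -2.15, where read abundance does not count. In aub and spnE, whose files are of the smaller kind, the log2 ratios were -1.29 and -1.93 by distinct sequences, with a mean of -2.25 by reads. Larger files therefore do not account for these 2 falls. Without krimp and vasa the difference by distinct sequences was -2.33, at an exact permutation p of 0.067, the smallest possible. Dilution by microRNA, 2S rRNA and contig reads is argued against, since they were left out where the difference was -2.15, but dilution by other background reads stays open, with a Spearman rho of 0.10 (permutation p = 0.69) between 2S rRNA share and signature over the 18 libraries. A requirement of the ping-pong cycle for aub, krimp, spnE and vasa may underlie the difference, as a hypothesis, and loss of germline cells or less mapped sequence of each kind was not tested.

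The changes of 7 microRNAs are weighed here because they run against a background expected to stay level. Sequence variants of different error rates stay open, since 100% of the called microRNAs kept their sign with no mismatches in the 16 bases compared, but these reads are variants outside those bases. Let-7, miR-100 and miR-125 had a mean log2 fold of 0.61, so the soma list did not fall as a whole. Among them only miR-100 was called, at 15 to 82 reads per library, and miR-1 and miR-277 rose too. Which cells the reads of let-7, miR-100 and miR-125 come from was not tested, so a loss of somatic cells stays open. More RNA breakdown in mutants would raise miR-1 where 2S rRNA rises, but the Spearman rho over the 9 pairs was -0.55 (permutation p = 0.13), with a Pearson r of -0.60 (permutation p = 0.090) that was -0.35 without the 2 pairs farthest from the median. A change in the make-up of the ovary, with fewer cells that express miR-318 and more that express miR-1, may lie behind the calls, and differences between the balanced heterozygote stocks and the mutants stay open as well.

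The aub heterozygote stood apart from the other heterozygotes with 178818 reads of 21 nt on assembled contigs per 1000000, a signal that no comparison of the report measures by itself, and with 27.5% of its 18 to 30 nt reads at exactly 21 nt, a linked value. They count in the length profile, where leaving them out with microRNA and 2S rRNA reads moved the log2 ratio of the aub pair from 0.60 to 0.33, and in the 13 libraries with at least 1000 such reads 47.9% to 52.2% of them lie on the plus strand of the 23 contigs. Double-stranded RNA cut into 21 nt duplexes may be their source, but 19 nt was the most frequent overlap in 9 of these 13 libraries, at 5.21% to 11.5% of overlaps from 10 to 21 nt over all 13, so the test leaves this open. The summed longest open reading frames of 6177 bases exceed the highest of 200 shuffles, 3972, which speaks for protein-coding sequence whose origin was not analysed. Carry-over of every contig in proportion from the aub heterozygote, limited by the contigs least seen, could supply at most 43.0% of the contig reads of the armi heterozygote, the krimp, piwi and spnE mutants and the flam, squ and zuc libraries, which argues against it as their main source, but in the krimp heterozygote and the armi mutant the limits of 72.3% and 99.8% leave it open.

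The armi heterozygote stood apart from the other heterozygotes in a family of abundant sequences beginning with A, at 14690 reads per 1000000 against at most 765 in the others. Of 8 measures examined over the 9 heterozygotes 3 were picked up in this way, and chance picks up about 1 in 20.

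Other splits of the libraries were counted for each test over many sequences. The libraries are paired by locus, and 8 splits part all 4 pairs of a class, too few for a share under 0.05. The real split gave 2405 tags at the germline loci and 82 at the soma and germline loci, and the highest other gave 0 at both. The remaining splits of the 32 counted keep some pairs together, and their highest was 4 at the germline loci. For the difference between the classes 2 of 35 splits gave as many tags at an unadjusted p under 0.05 as the real 1199, with 1212 in the highest other, so chance cannot be excluded. For microRNAs 1 of 100 assignments within pairs, the real one, gave as many as the 7 called, with at most 3 in another. Of the other assignments 5 gave any call. This argues against chance for the number of calls, at the smallest share that 100 assignments allow, but not for each single microRNA.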

How the results depend on the processing

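Chosen after seeing the data were: for length and 5′ U, microRNA, 2S rRNA and contig reads left out, and for 5′ U the A-starting family left out; for ping-pong, those reads kept, the mean, 24 to 28 nt, the top complementary pair left out, and squ by distinct sequences; for 2S rRNA, distinct sequences; tags of at least 20 reads in all; microRNAs scaled by all reads; all other definitions of the tag sets; and krimp and vasa (for microRNAs also squ) left out. The cause of the differences was not tested.

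The fall in 5′ U and the rise in 2S rRNA passed the threshold in each alternative measure tried, though not within the 6 pairs of smaller files by reads. The length profile also passed by distinct sequences (-0.22) and without microRNA, 2S rRNA and contig reads (-0.21). The class difference in 5′ U, 4.14 points, reversed at 24 to 28 nt (-1.06) and without those reads (-2.93). The class difference in ping-pong passed by distinct sequences (-2.15, and -1.89 with squ), at 24 to 28 nt (-2.82) and without the top complementary pair (-2.63). It did not with squ by reads (-1.71), with listed reads kept (-1.58), with the mean in place of the median (-2.24) or without krimp and vasa (-2.87, and -2.33 by distinct sequences). With each locus left out it ranged from -2.56 (krimp, which passed) to -1.70 (aub), and the mean over pairs from -0.52 to -0.08.

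At the germline loci tags numbered 174 higher with microRNA reads as library size, 229 higher with DESeq2, 1328 lower with squ and 1085 lower by distinct sequences, and 0 higher and 0 lower without krimp and vasa. At the other loci 3 were higher and 0 lower with microRNA reads as library size, 175 higher by distinct sequences, 17 higher and 1 lower at 20 reads in all, 267 higher and 289 lower with DESeq2, 5 lower with TMM, 26 lower with squ, and 2 higher and 0 lower without krimp and vasa. Between the classes 2 were higher and 240 lower by distinct sequences, and 2 higher and 256 lower with DESeq2. The filter kept 9018 tags in the main setting, 10766 with microRNA reads as library size and 7152 without krimp and vasa. It kept 4659 with squ among the germline loci and 3578 by distinct sequences. Fewer calls in these 2 settings are thus over fewer tags and need not mean a weaker result. With each locus left out the germline loci had 112 to 523 higher and 671 to 2329 lower, the others 0 to 348 higher and 0 to 108 lower, and the difference 0 higher and 0 to 52 lower. The flam set differed by 2.12 at 50 heterozygote reads, and no other tag set test passed, nor can 3 loci against 3 pass. Tag responses were more alike within classes than between them by 0.0676 in mean correlation (exact permutation p = 0.057), and by -0.0367 without krimp and vasa.

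MicroRNAs numbered 2 higher when scaled by all reads and 2 higher without krimp, vasa and squ, and with each locus left out 3 to 4 higher and 1 to 4 lower. Of the settings of the 7 called, 0 reversed and 22 lost the call.

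The Piwi immunoprecipitate had 94.5% of 23 to 29 nt and 67.5% with 5′ U by distinct sequences, and D. erecta 17.2% microRNA reads with 3 mismatches. Alignment with 0 or 1 mismatch, reads split among families, the soma and germline family settings, the cluster settings and tags without a minimum were not run. In simulated counts with 200 of 9018 tags changed, 0% of 2-fold and 4-fold changes were recovered. The real data gave 2405 calls at the germline loci, so the simulation differs from them in the share of tags changed. It also gave each tag the same mean in all libraries, apart from library size and the changes made, without differences between loci. The smallest fold that the tag calls cover is therefore not known from it, and the cause was not tested.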

Other observations

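The test of the flam set was chosen before its result was seen, and that of the family of abundant sequences after it.

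If 1 set of tags depended on all loci alike, the flam set would fall with the other tags in the armi, piwi and zuc mutants. The difference of medians from the other tags was -0.88 in piwi and -0.87 in zuc but -0.34 in armi, the highest of the 3, which does not reach the bound of -0.5 set for each, so the test leaves the hypothesis open.

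A family of abundant sequences that begin with A and share a core was higher in all 9 mutants, by 5.14 on the log2 scale (SD 2.44, n = 9 pairs; exact sign-flip p = 0.0039, the smallest possible). It took 218042 reads per 1000000 in the aub mutant and 311 in its heterozygote, 34788 against 200 in vasa and 24281 against 344 in piwi. In the armi pair it was high in both libraries, at 26433 in the mutant and 14690 in the heterozygote. Its origin was not analysed here.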
